A study of Homo sapiens with 4 samples.

How the data were processed

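Gene expression was measured on 4 single-colour Affymetrix arrays of MCF-7 cells, an established estrogen receptor-positive human breast cancer line, kept for 90 h in normoxia (2 arrays), hypoxia (1 array) or anoxia (1 array). The labels do not say whether the arrays came from separate cultures, and they give no batch or scan date. The spread between the normoxia arrays may therefore be technical only, and every p-value below measures differences against that spread.

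The deposited values are log2 expression values made by the authors with Affymetrix Expression Console and the RMA method, per the submitters' processing notes, which give no versions. RMA corrects the background, normalizes probe values across arrays and summarises the probes of each transcript cluster, the unit the array measures. The log base is not stated in the sources used here, and log2 was taken from the method and from the range of the values, 1.45 to 13.99. The values are positive and not centred on any gene, and an array of 1 colour leaves no direction to settle. Array medians were 4.88 and 4.84 for normoxia, 4.94 for hypoxia and 4.92 for anoxia. Sorted values of any pair of arrays differed by at most 0.144. Scanner files were not used here, so signal over background was not measured, and the number of arrays limits the precision.

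The table held 44258 transcript clusters. Of these, 15835 had 1 gene symbol in the platform annotation used here, 0 had several and 28423 had none in that annotation, which leaves them unnamed here rather than without a gene. All 15835 gene IDs matched the RefSeq gene table of assembly GRCh38.p14, and 0 symbols differed from it. The genome build behind the array annotation was not stated in the sources used here, so no positions are given. For the 651 genes with more than 1 cluster, the cluster with the highest mean over the 4 arrays was taken, which left 14812 genes. Among called genes with several clusters, 6 of 24 in hypoxia and 5 of 42 in anoxia had another cluster of opposite sign. The probe names held no control prefix (0 names), so no control probes were set apart by name.

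All 4 arrays entered 1 linear model with a mean per group, fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, eBayes with a trend of variance on expression). The normoxia pair gives the 1 residual degree of freedom per gene, moderation adds 4.15, and the lone hypoxia and anoxia arrays were assumed to vary as the normoxia pair does. A gene was called, written as rose or fell, at a Benjamini-Hochberg adjusted p under 0.05 over the 14812 genes together with a change of at least 2-fold. Standard errors are limma's moderated ones, with a median of 0.16 on the log2 scale against normoxia. Genes at least 2-fold from each normoxia array were also counted by size, with no test. The submitters' notes name no statistical test.

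The groups, the test, 27 gene lists with 545 memberships (531 different genes, so some genes sit in more than 1 list), the rule for naming genes and the alternative settings were fixed before the data were examined. Of the memberships, 301 had a tested gene, and list counts below are out of tested members only. Tested were 15 of 69 oxidative phosphorylation subunits, 8 of 20 glycolysis genes and 5 of 12 leukocyte markers, for example. Members not tested were not read. For each list the calls were counted over all genes and with p adjusted over the list alone. The median change of each list was placed as a percentile among 10000 random lists of the same size matched on mean expression in 20 bins, which describes these arrays and gives no p. The genes named are the 8 largest rises and the 8 largest falls called against normoxia and at least 2-fold from each normoxia array, 5 and 5 by size between anoxia and hypoxia, up to 4 members per list, and a fixed set for oxygen response and drug response. In that set CA9, HIF1A, SLC2A1, ABCB1 and ABCG2 had no named cluster here. The 5 marker lists of cell types (luminal, basal, mesenchymal, leukocyte and endothelial) were among the 27.

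Alternatives covered the mean of all clusters of a gene, the upper part of the genes by expression, median centring, quantile normalization and cyclic loess of the arrays, other variance priors, other thresholds, other fold sizes, and leaving out each normoxia array, which leaves no residual degree of freedom and hence sizes only. A fit over all transcript clusters was added after the data were seen. The limma steps were tested on simulated data with 14812 genes, 200 of them changed, in 5 runs. In the simulated hypoxia comparison 99.8% of genes changed by 1.5 on the log2 scale were recovered with 3.8 false calls on average, and in the simulated anoxia comparison 100% with 2.6. Of genes changed by 3, 100% were recovered in both. These runs tested the steps and give no error rate for the calls on the real arrays. Those calls rest on the assumption that the lone arrays vary as the normoxia pair does. Plots were drawn with matplotlib 3.10.9.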

Results

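The arrays asked whether MCF-7 breast cancer cells kept for 90 h in low oxygen or without oxygen carried the transcriptional response to oxygen loss. Normoxia had 2 arrays, hypoxia 1 and anoxia 1, and each array gave 44258 transcript clusters, of which 14812 genes were tested. Across all clusters the normoxia arrays correlated at 0.993 and the hypoxia and anoxia arrays at 0.991. Correlations between a low-oxygen and a normoxia array lay from 0.977 to 0.985. Clusters are not independent replicates, and these values describe the 4 arrays only.

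In hypoxia, genes of the oxygen response rose and genes of DNA replication fell. NDRG1, a stress-responsive gene induced by low oxygen, rose by 3.59 ± 0.18 on the log2 scale (SE, limma adjusted p = 0.00386) from 6.25 ± 0.26 in normoxia (SD, n = 2). VEGFA, the main angiogenic growth factor, rose by 1.82 ± 0.10 from 7.58 ± 0.06, and ADM, which encodes the vasodilator peptide adrenomedullin, rose by 2.85 ± 0.12 from 5.79 ± 0.04. GINS2, a subunit of the replicative helicase, fell by 1.57 ± 0.12 from 10.89 ± 0.17. In all, 252 genes rose and 179 fell in hypoxia against normoxia (1 array against 2). On median-centred arrays the counts were 233 and 250, so that the share of rises among calls went from 58.5% to 48.2%.

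The largest rises in hypoxia were TMEM156 (4.77 ± 0.40, SE), RGCC, a regulator of the cell cycle (4.03 ± 0.19), the chemokine gene CCL22 (3.68 ± 0.31), NDRG1, CEACAM5, which encodes carcinoembryonic antigen (3.36 ± 0.09), ANGPTL4, an inhibitor of lipoprotein lipase (3.06 ± 0.21), SAMD4A (2.96 ± 0.11) and RIMKLA (2.93 ± 0.11). TMEM156 and RGCC lay at 3.84 ± 0.69 and 4.01 ± 0.24 in normoxia (SD, n = 2), below the median of all clusters, 4.86, so that the floor under their changes is unknown here and in anoxia. CEACAM5 has close relatives in sequence, and its signal may be shared with them. The largest falls were MGP, an inhibitor of calcification (-3.18 ± 0.17), TMT1A (-2.46 ± 0.16), BCL2, the survival gene of the mitochondrial apoptosis pathway (-2.13 ± 0.12), ANXA6 (-2.12 ± 0.26), PLBD1 (-2.10 ± 0.16), SFXN2 (-2.10 ± 0.13), MMP16 (-2.09 ± 0.25) and BMP5 (-2.06 ± 0.14). Limma adjusted p-values of these 16 genes ran from 0.00232 for CEACAM5 to 0.0148 for MMP16.

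Among HIF target genes, 17 of 21 tested rose in hypoxia and 0 fell, with a median of 1.60 (percentile 100 of the random lists). In glycolysis 4 of 8 rose, namely HK2, the first enzyme of the pathway (2.88 ± 0.15), PGK1 (1.38 ± 0.11), LDHA (1.26 ± 0.12) and TPI1 (1.02 ± 0.15), with a median of 0.90 (percentile 100). On median-centred arrays TPI1 stood at 0.94 and passed below the size set for a call. Of 5 HIF pathway components, 3 rose: EPAS1, which encodes the HIF-2 alpha subunit (1.87 ± 0.16), and the oxygen-sensing prolyl hydroxylases EGLN3 (1.60 ± 0.16) and EGLN1 (1.54 ± 0.08). The collagen modification list had 2 of 7 members higher, the lysyl oxidase-like genes LOXL2 (2.83 ± 0.30) and LOXL1 (1.27 ± 0.09). The oxygen-dependent demethylases had 2 of 15, KDM3A (1.63 ± 0.10) and KDM7A (1.24 ± 0.10), with a median of 0.36 (percentile 99.95). EGLN1, EGLN3 and KDM3A are members of the HIF target list too, so those rises are not separate from its count. All these counts were equal when adjusted over the list alone.

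Of 19 DNA replication genes tested, 11 fell in hypoxia and 0 rose, with a median of -1.15 (percentile 0). MCM10 fell by 1.64 ± 0.14, CDC6, which loads the helicase at origins, fell by 1.62 ± 0.12, and FEN1, the flap endonuclease, fell by 1.34 ± 0.19. No mitosis gene was called (0 of 21 fell or rose), with a median of -0.35 (percentile 0.05) and 20 of 21 values below 0. In the list of the estrogen receptor and its targets 4 of 17 fell and 1 rose, with a median of -0.39 (percentile 0.03). PDZK1 fell by 1.86 ± 0.32, PGR, the progesterone receptor gene, fell by 1.69 ± 0.18, RET fell by 1.57 ± 0.22 and CXCL12 fell by 1.25 ± 0.11. TFF3, named after its values were seen, rose (1.05 ± 0.20), but on median-centred arrays the list had 0 rises and 5 falls. ESR1, the estrogen receptor gene, stood at -0.73 ± 0.09 (limma adjusted p = 0.0143), below the size set for a call. Adjusted over the list alone, these counts were the same.

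The ATF4 and amino acid response list had 4 of 12 members that rose in hypoxia and 1 that fell. VLDLR rose by 2.11 ± 0.15, DDIT3, a transcription factor of the stress response, rose by 1.86 ± 0.14, TRIB3 rose by 1.39 ± 0.09 and ATF3 rose by 1.25 ± 0.16, while CTH, named after its values were seen, fell (-1.13 ± 0.17). Among 13 p53 targets, 1 rose (GDF15, 1.64 ± 0.24), and among 16 autophagy genes 1 rose (ATG16L1, 1.11 ± 0.10). The metallothioneins, a family of near-identical genes whose signals cannot be separated with certainty, had 1 of 7 called (MT1X, 1.21 ± 0.20). Of 15 cholesterol synthesis genes 1 fell, TM7SF2 (-1.13 ± 0.11). No member was called (0) among the 15 oxidative phosphorylation subunits tested of 69 listed (median -0.18, percentile 8.38, 15 of 15 below 0). None was called among 10 tricarboxylic acid cycle genes (median -0.24), 12 ribosome biogenesis genes (median -0.23) or 8 endoplasmic reticulum chaperones (0 each). The 9 NF-kB and inflammatory genes and 15 interferon-stimulated genes also gave 0 calls. Adjusted over the list alone, the counts of all these lists were unchanged. At an unadjusted level, 4207 of all 14812 genes had a limma p under 0.05 in hypoxia.

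Drug-related genes were examined because the arrays accompanied a screen of chemotherapeutic drugs. Of 19 targets and activating enzymes of anticancer drugs, 1 rose in hypoxia, NAMPT, the enzyme of NAD salvage (1.08 ± 0.09), and 1 fell, BCL2. The list median was -0.25 (percentile 1.86). By its fixed membership the list shares TYMS, RRM1 and RRM2 with the DNA replication list and TOP2A with the mitosis list. Its median is therefore not separate from theirs. TOP1 stood at 0.10 ± 0.08 and TOP2A at -0.02 ± 0.11, both topoisomerase genes targeted by drugs. The sign of TOP2A was not stable, at 0.09 against normoxia replicate 1 alone and 0.006 after cyclic loess. NAMPT stood at 0.93 with the mean of all its clusters, below the size set for a call. Of the drug efflux transporter list only MVP of 10 members had a named cluster, at -0.68 ± 0.17 in hypoxia and -0.33 ± 0.17 in anoxia, and it was not called. MVP stood at -0.83 and -0.47 against normoxia replicate 1 alone, and at -0.54 and -0.18 against replicate 2 alone. It encodes the major vault protein, which is not itself a transporter, so no efflux transporter was read here. These counts were the same adjusted over the list alone.

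Cell type markers and reference genes were read in the same way. In hypoxia CD68 rose by 1.79 ± 0.14 (1 of 5 leukocyte markers, list median 0.37, percentile 97.7, but 0.16 against normoxia replicate 1 alone and 0.59 against replicate 2 alone), EGFR by 1.87 ± 0.13 (1 of 3 basal markers) and FN1, the fibronectin gene, by 1.16 ± 0.09 (1 of 9 mesenchymal markers, 2 adjusted over the list alone). No luminal marker of 9 and no endothelial marker of 5 was called (0 each). PGK1 was the 1 of 5 reference genes that rose. Adjusted over the list alone, the other counts did not differ.

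The limit of the hypoxia calls lies in the spread, which only the normoxia pair supplies. With 1 common variance prior and no trend on expression, limma called 66 rises and 23 falls, and the list counts went to 10 HIF targets, 3 ATF4 targets and 1 each of glycolysis, HIF pathway, DNA replication, drug target, demethylase and basal marker genes. No call was left (0) in the estrogen receptor, collagen, p53, autophagy, cholesterol, metallothionein, reference, leukocyte and mesenchymal lists, and TMEM156, CCL22, EPAS1, LDHA, PGK1, LOXL2, GINS2, MCM10, PGR, RET and GDF15 were among the named genes no longer called. By size against normoxia replicate 2 alone, 0 metallothioneins and 0 estrogen receptor targets were at least 2-fold higher in hypoxia, 2 mesenchymal markers (2 were called under each of the 3 scalings) and 1 interferon-stimulated gene were, and against replicate 1 alone 1 cholesterol synthesis gene was.

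**Figure D1:**
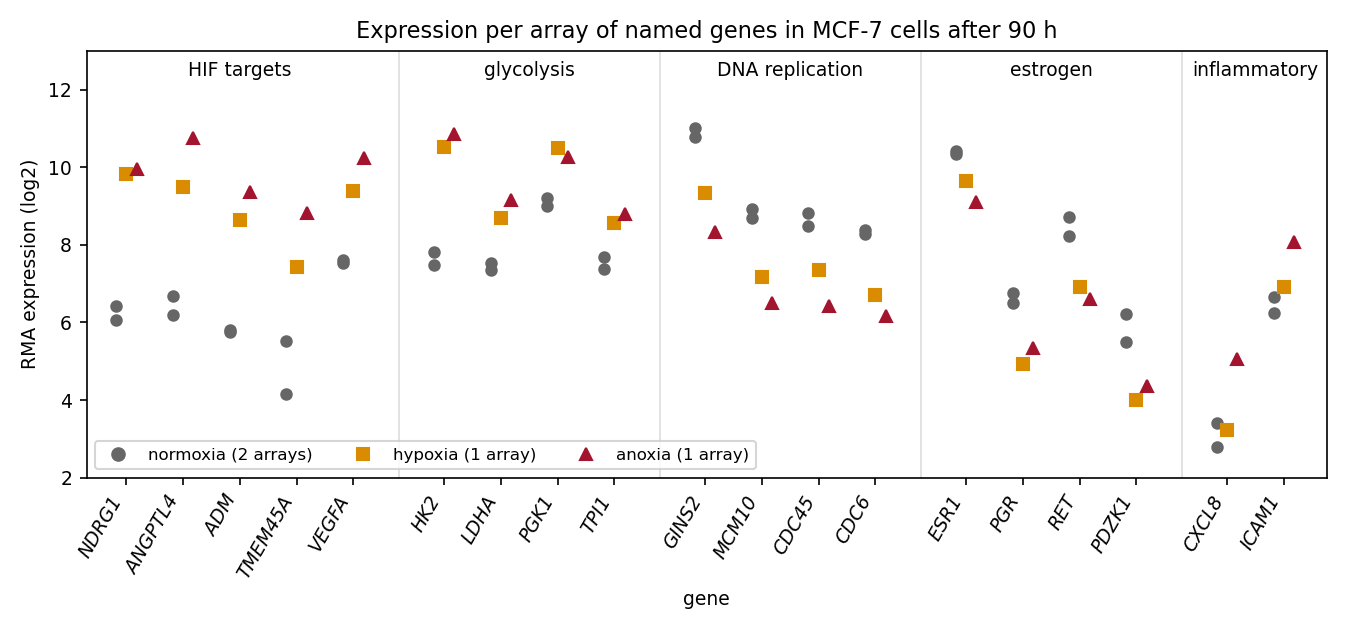
Log2 RMA expression of named genes on each array, with circles for the 2 normoxia arrays, squares for hypoxia and triangles for anoxia (1 array each). NDRG1 lay at 6.25 on average in normoxia and rose by 3.59 in hypoxia and 3.71 in anoxia, while GINS2 fell by 1.57 and 2.55.

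In anoxia, genes of the oxygen response rose, and genes of DNA replication and mitosis fell. ADM rose by 3.57 ± 0.12 (SE, limma adjusted p = 0.00124), NDRG1 by 3.71 ± 0.18 and VEGFA by 2.66 ± 0.10. The replication genes GINS2 and MCM10 fell by 2.55 ± 0.12 and by 2.31 ± 0.14, and CDCA8, a subunit of the chromosomal passenger complex of mitosis, fell as well (-1.40 ± 0.09). ESR1 fell by 1.28 ± 0.09 from 10.38 ± 0.05 in normoxia (SD, n = 2). In all, 440 genes rose and 394 fell in anoxia against normoxia (1 array against 2). The counts were 489 and 323 after cyclic loess, 393 and 473 on median-centred arrays and 309 and 333 in the upper part of the genes by expression, so that whether rises or falls were more frequent depended on the setting.

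The largest rises in anoxia were TMEM156 (5.21 ± 0.40, SE), RGCC (5.02 ± 0.19), ANGPTL4 (4.32 ± 0.21), TMEM45A (3.96 ± 0.54), NDRG1, ADM, MMP13, which encodes a collagenase (3.52 ± 0.42), and GEM, which encodes a small GTP-binding protein (3.43 ± 0.30). The largest falls were TMT1A (-3.34 ± 0.16), GINS2, the chemokine gene CXCL14 (-2.45 ± 0.33), BCL2 (-2.44 ± 0.12), ANXA6 (-2.42 ± 0.26), SFXN2 (-2.40 ± 0.13), CDCA7 (-2.33 ± 0.23) and MCM10. TMEM45A lay at 4.84 ± 0.96 in normoxia (SD, n = 2), also below the median of all clusters. Limma adjusted p-values of these 16 genes ran from 0.00124 for ADM to 0.00962 for TMEM45A.

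In anoxia 17 of 21 HIF targets rose and 0 fell, with a median of 2.09 (percentile 100). Glycolysis had 4 of 8 that rose, HK2 (3.22 ± 0.15), LDHA (1.72 ± 0.12), TPI1 (1.27 ± 0.15) and PGK1 (1.15 ± 0.11), with a median of 0.94 (percentile 100). Of 5 HIF pathway components EPAS1 (2.60 ± 0.16) and EGLN1 (1.55 ± 0.08) rose, and EGLN3 stood at 0.92 ± 0.16. LOXL2 (3.42 ± 0.30) and LOXL1 (1.14 ± 0.09) were the 2 of 7 collagen modification genes that rose. KDM3A (2.28 ± 0.10) and KDM7A (1.38 ± 0.10) were the 2 of 15 demethylases, with a median of 0.51 (percentile 100). EGLN1 and KDM3A also count among the HIF targets. These counts were the same adjusted over the list alone.

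DNA replication had 15 of 19 members that fell in anoxia, with a median of -1.78 (percentile 0), among them CDC45 (-2.25 ± 0.17) and CDC6 (-2.15 ± 0.12). Mitosis had 11 of 21 that fell and 0 that rose, with a median of -1.04 (percentile 0), among them the kinase gene AURKB (-1.38 ± 0.12) and the spindle motor genes KIF23 (-1.34 ± 0.13) and KIF11 (-1.33 ± 0.15). Of the 17 estrogen receptor genes 5 fell and 0 rose, with a median of -0.56 (percentile 0.01; -0.34 in the upper part of the genes by expression), among them RET (-1.88 ± 0.22), PDZK1 (-1.51 ± 0.32) and PGR (-1.28 ± 0.18). Of 12 ribosome biogenesis genes RRS1 alone fell (-1.27 ± 0.11), with a list median of -0.54 (percentile 0.13). Adjusted over the list alone, the counts were the same.

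Among NF-kB and inflammatory genes 2 of 9 rose in anoxia, the chemokine gene CXCL8 (1.96 ± 0.30, from 3.09 ± 0.44 in normoxia, SD, n = 2) and the adhesion molecule gene ICAM1 (1.61 ± 0.20), with a median of 0.68 (percentile 99.98). The ATF4 list had 4 of 12 that rose and 1 that fell, with DDIT3 at 2.32 ± 0.14, VLDLR at 1.97 ± 0.15, ATF3 at 1.84 ± 0.16, TRIB3 at 1.79 ± 0.09 and a list median of 0.36. Among p53 targets 2 of 13 rose, GDF15 (1.90 ± 0.24) and the pro-apoptotic gene PMAIP1 (1.87 ± 0.16). ATG16L1 was the 1 of 16 autophagy genes that rose (1.16 ± 0.10, list median 0.23), and MT1X the 1 of 7 metallothioneins (1.23 ± 0.20). Cholesterol synthesis had 2 of 15 that fell, TM7SF2 (-1.13 ± 0.11) and EBP (-1.01 ± 0.12), with a median of -0.29 (-0.47 against normoxia replicate 2 alone). USP18 was the 1 of 15 interferon-stimulated genes that fell (-1.01 ± 0.12), while the list median was 0.19 and turned to -0.15 among the more highly expressed genes and to -0.04 against normoxia replicate 1 alone. After cyclic loess EBP stood at -0.92 and USP18 at -0.92, and after quantile normalization both at -0.96, below the size set for a call. Adjusted over the list alone, every count in this paragraph was the same.

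No tested subunit of oxidative phosphorylation was called in anoxia (0 of 15, with 69 listed). All 15 values lay below 0 with a median of -0.34 (percentile 2.59). The tricarboxylic acid cycle genes gave 0 of 10 calls and a median of -0.47 (percentile 1.38), with 10 of 10 below 0, and the endoplasmic reticulum chaperones 0 of 8 and -0.34. COX6C stood at -0.90 ± 0.18 and IDH3A at -0.79 ± 0.15. By limma, 4974 of the 14812 genes had an unadjusted p under 0.05 in anoxia, and adjusted over the list alone these counts stayed at 0.

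Of the 19 drug targets and activating enzymes, BCL2 and RRM2, a subunit of ribonucleotide reductase (-1.26 ± 0.15), fell in anoxia and NAMPT rose (1.03 ± 0.09), with a median of -0.55 (percentile 0). That median is not separate from those of the DNA replication and mitosis lists, which share members with this list. TOP1 stood at 0.14 ± 0.08 and TOP2A at -0.67 ± 0.11. NAMPT stood at 0.88 with the mean of all its clusters, at 0.97 on median-centred arrays and at 0.99 after quantile normalization, each below the size set for a call. Adjusted over the list alone, the counts were the same.

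Among cell type markers in anoxia, CD68 rose by 2.21 ± 0.14 (1 of 5 leukocyte markers, list median 0.52, percentile 99.7, but 0.30 against normoxia replicate 1 alone) and EGFR by 2.61 ± 0.13 (1 of 3 basal markers). Of 9 mesenchymal markers 3 rose, FN1 (2.16 ± 0.09) and the transcription factors SNAI1 (2.08 ± 0.13) and SNAI2 (2.05 ± 0.31), with a median of 0.29 (percentile 98.8, but 0.19 against normoxia replicate 1 alone). The median normoxia level of this list was 3.93, below the median of all clusters, 4.86. SNAI2 was no longer called at a limma adjusted p under 0.01. ESR1 was the 1 of 9 luminal markers that fell. Endothelial markers gave 0 calls of 5. PGK1 was again the 1 of 5 reference genes that rose. All these counts were equal adjusted over the list alone. Without the variance trend PDZK1 and MT1X were no longer called in anoxia.

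Some small list counts in anoxia moved with the scaling or the control array. Autophagy had 3 rises after cyclic loess, and the drug target list had 0 rises and 3 falls on median-centred arrays. By size against normoxia replicate 2 alone, 0 metallothioneins, 2 autophagy genes and 1 interferon-stimulated gene were at least 2-fold higher and 4 drug targets lower. Against replicate 1 alone, 0 drug targets and 1 cholesterol synthesis gene were higher, and 0 ATF4 targets, 0 interferon-stimulated genes, 1 cholesterol synthesis gene and 1 oxidative phosphorylation subunit were lower.

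**Figure D2:**
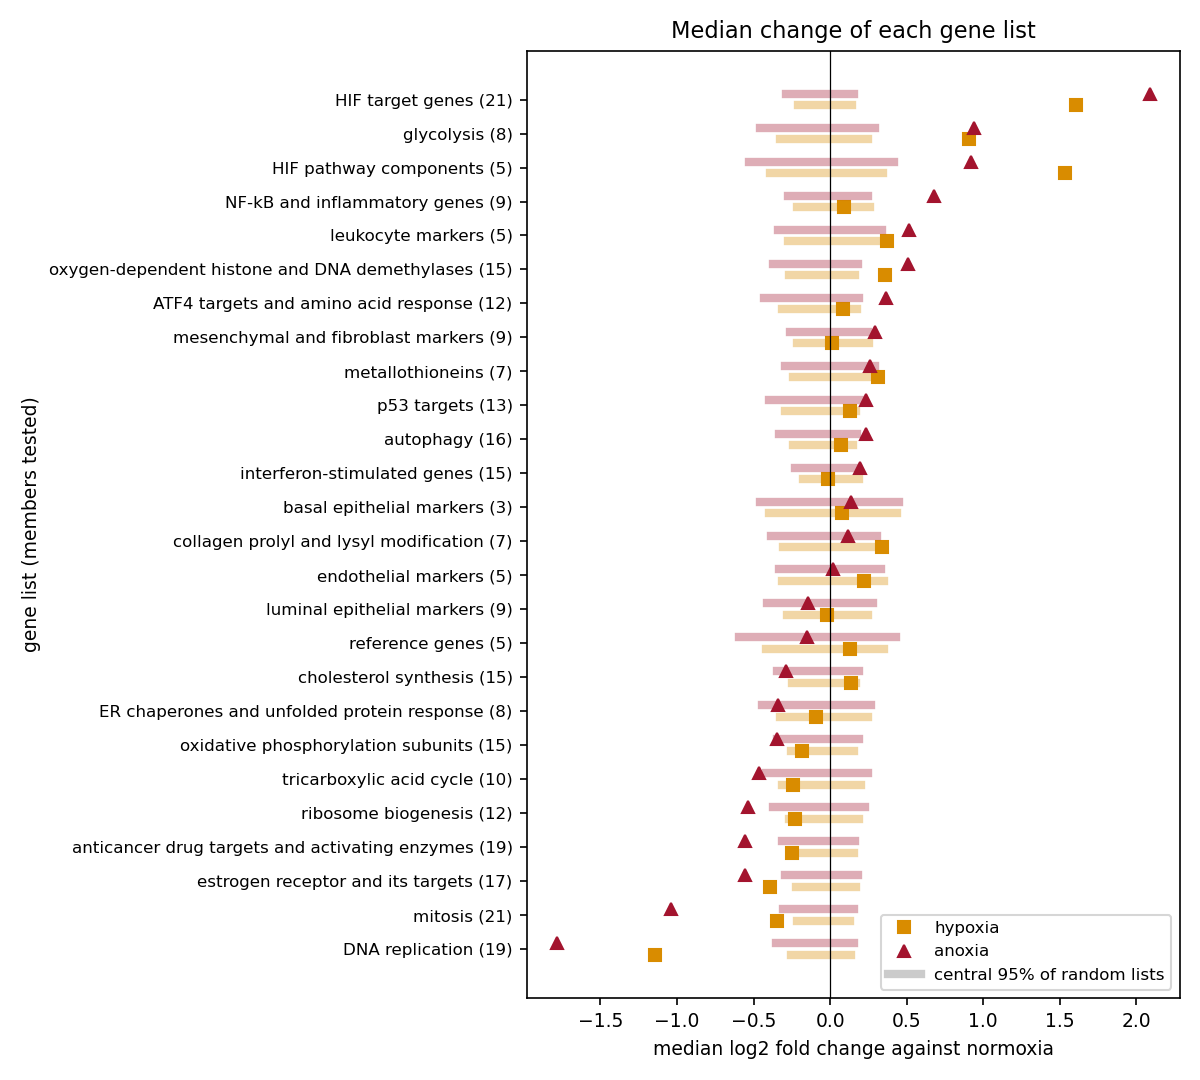
Median log2 fold change of each gene list against normoxia, with squares for hypoxia, triangles for anoxia and bars for the central 95% of 10000 random lists. HIF targets lay at 1.60 and 2.09 and DNA replication at -1.15 and -1.78, outside the bars.

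Between anoxia and hypoxia no gene passed the test, and the genes named here were ranked by size. Highest in anoxia was GEM, at 2.38 ± 0.35 on the log2 scale (SE, limma adjusted p = 0.201). It was followed by the chemokine gene CCL2 at 2.34 ± 0.20 (adjusted p = 0.182), CEMIP, which takes part in hyaluronan breakdown, at 2.08 ± 0.16, CXCL8 at 1.81 ± 0.34 and LINC01239 at 1.78 ± 0.15. Lowest by size were MIR4718 (-2.02 ± 0.45), ZNF732 (-1.53 ± 0.33), MIR3685 (-1.51 ± 0.35), MIR4320 (-1.40 ± 0.25) and MED27 (-1.34 ± 0.31). In this comparison 1 array stood against 1. By size alone 71 genes were at least 2-fold higher in anoxia and 28 lower.

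Limma called 0 genes either way between anoxia and hypoxia, with a smallest adjusted p of 0.182 and 1833 genes at an unadjusted p under 0.05. It also called 0 without the variance trend, but 54 higher and 5 lower after cyclic loess, 66 and 16 on median-centred arrays, and 19 and 0 after quantile normalization, and 19 genes were higher under all 3 scalings. GEM, CCL2, CEMIP, SNAI1 and FN1 were among the 19.

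List medians between anoxia and hypoxia were -0.67 for mitosis (21 of 21 below 0, percentile 0), with CDK1, the mitotic kinase gene, at -1.02 ± 0.17, and -0.62 for DNA replication (19 of 19 below 0, percentile 0). Cholesterol synthesis had a median of -0.46, with 15 of 15 below 0 (percentile 0) and MVK at -0.70 ± 0.15. The median of the NF-kB and inflammatory genes was 0.51 (8 of 9 above 0, percentile 99.99), with ICAM1 at 1.14 ± 0.23. HIF targets had a median of 0.29 (18 of 21 above 0, percentile 100), with ANGPTL4 at 1.26 ± 0.25 and VEGFA at 0.84 ± 0.12. Over all genes 0 members of any list passed. After cyclic loess, and likewise on median-centred arrays, 2 inflammatory genes, 1 HIF target, 1 p53 target and 2 mesenchymal markers were called higher, and after quantile normalization 2 mesenchymal markers. With p adjusted over the list alone, 2 inflammatory genes, 1 HIF target, 1 p53 target and 1 mesenchymal marker were higher and 1 mitosis gene lower.

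Changes in hypoxia and in anoxia ran in the same direction for most genes called in either. Of the 894 genes called in hypoxia or anoxia, 98.7% had the same sign in both and 81.8% (731) had the larger absolute change in anoxia. Genes chosen in this way share the normoxia arrays, so the shares were also read without effects: the 894 genes of smallest p had the same sign in 77.3% on average (at most 80.5% in 20 simulations of unchanged groups), against 99.3% observed for genes ranked so. Of them 49.5% on average (at most 51.5%) were larger in anoxia, against 83.2% observed. The simulations gave the lone hypoxia and anoxia arrays the same spread, which by itself fixes the simulated share near that value. A noisier anoxia array would also raise the share, and with 1 array this could not be tested. Genes that rose in both numbered 227, led by TMEM156 and RGCC, and genes that fell in both numbered 144, with TMT1A and BCL2 among them. No gene was called in opposite directions (0). Genes that rose in hypoxia had a median of 1.36 there and of 1.61 in anoxia, and genes that fell had -1.23 and -1.29.

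The fold changes of the 14812 genes correlated across genes at r = 0.81. In 100 simulations of unchanged groups that shared simulated normoxia arrays, r was 0.334 on average and at most 0.368. All simulated arrays had the same spread per gene, which by itself fixes the simulated r near that average. The covariance of the observed fold changes was 0.174 against 0.00895 in the simulations, a difference of 0.165. The difference between the actual normoxia arrays gives a covariance of 0.0132, above that of the simulations. Genes are not independent replicates. Independent lists of the same lengths would share 7.49 rises and 4.76 falls. Simulated unchanged groups shared 0.4 calls on average, but only 3 genes were called there in hypoxia and 2.15 in anoxia on average. That shared count therefore cannot show how much overlap the shared controls add. With the normoxia pair split into 1 array for each comparison, no array was shared, though a deviation common to both normoxia arrays would remain. For the splits possible, r was 0.69 and 0.724 and the covariance 0.157 and 0.164. The overlap of calls was not recomputed in this way, since 1 array leaves no spread, and part of its excess may come from the shared controls. By size, 219 genes were at least 2-fold higher and 139 lower in hypoxia than in each normoxia array, 369 and 290 in anoxia, against 21 and 6 between the normoxia arrays themselves. Against normoxia replicate 2 alone the lower counts were 239 and 483, and against replicate 1 alone 172 and 343.

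**Figure D3:**
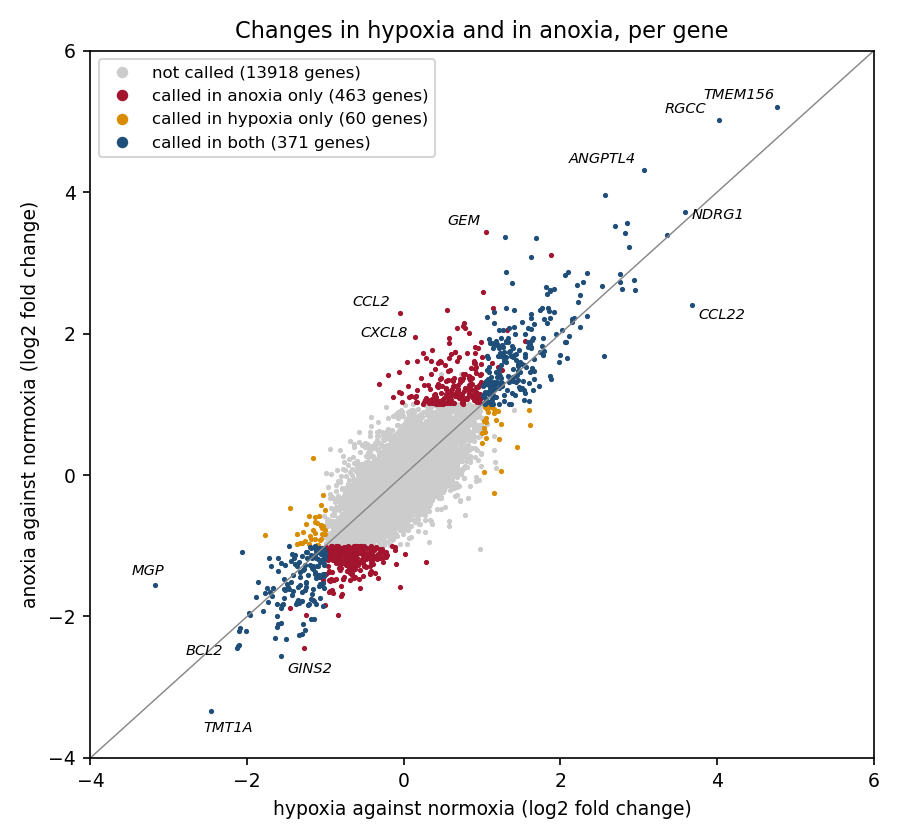
Log2 fold change in anoxia against that in hypoxia, 1 point per gene, coloured by the calls against normoxia, with a line of equal change. Of the 894 called genes, 371 were called in both and 731 had the larger absolute change in anoxia.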

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

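All tests in this part but the 2 on intensity-dependent bias were chosen after the result was seen. Transcript clusters with no gene name here lay outside the comparisons, and they held signal above the level between control arrays. In hypoxia 372 of 28423 such clusters were at least 2-fold from both normoxia arrays, 252 higher and 120 lower. In anoxia 713 were, 441 higher and 272 lower. Between the normoxia arrays 150 differed by as much, 72 higher and 78 lower.

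DNA replication genes were lower in anoxia than in normoxia, with a median of -1.78 over 19 genes. A bias that follows intensity was argued against: after subtracting the running median of genes of like expression the list median stayed at -1.67. A fault of the anoxia array alone was argued against too, since the separate hypoxia array gave -1.15. A lower share of dividing cells that lowers replication and mitosis genes alike stays open: the replication median lay below the mitosis median by a difference of -0.75, with a bootstrap interval over genes from -1.06 to -0.08 that includes small differences. Lower oxygen itself, the condition the design names, also stays open, and culture or handling differences between the arrays were not given in the labels and not tested.

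The fold changes in hypoxia and anoxia correlated across genes at 0.81. The shared normoxia arrays, as the whole cause, were argued against: the variance of their difference accounts for 7.56% of the observed covariance. Intensity-dependent bias was argued against as well, since r stayed at 0.807 after subtracting the running median of genes of like expression. A difference in culture, processing or hybridisation that set both low-oxygen arrays apart from the normoxia pair is not given in the labels and could not be tested, and a shared response to low oxygen likewise stays open.

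CCL22 and CCR1, chemokine system genes usual in leukocytes, were higher in hypoxia, by 3.68 and 2.55, and in anoxia, by 2.40 and 1.68; CCR1 was named after its values were seen. For RNA of leukocytes, 1 of 5 leukocyte markers rose in hypoxia, CD68, a lysosomal protein gene that other cells also express, while the marker median in anoxia was 0.52 (percentile 99.7), but 0.30 against normoxia replicate 1 alone, and 4 of 5 markers were above 0 against either replicate alone. For RNA of monocytes or macrophages, the largest change among CD14, LYZ and TYROBP in hypoxia was 0.37 (0.16 against normoxia replicate 1 alone and 0.59 against replicate 2 alone), and in anoxia CD14 stood at 0.70 and TYROBP at 0.52 (0.30 against replicate 1 alone). These markers cannot tell either source apart from a response of the cancer cells. Those that did not rise were dim, and signal over background was not measured. Their median level in normoxia, 4.74, lay below the median of all clusters, 4.86. A low level alone does not prevent a rise, since CCL2, at 4.42 in normoxia, rose by 2.29 in anoxia. The labels name MCF-7 cells and no leukocytes. A response of the cancer cells was itself not tested.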

How the results depend on the processing

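The fit over all transcript clusters was chosen after the data were seen, and all other alternatives before. Of 52 list medians followed, 7 changed sign under some alternative, and so did 6 of the 233 named gene changes followed, of which 0 were called. A called change, at least 2-fold by definition, had little room to change sign. Over the 8 alternatives that gave a call for them, 57 of 1817 named gene results lost their call, 8 gained one and 1752 did neither. Only 108 of the 233 named changes were called and could lose a call. Leaving out the variance trend alone ended 30 of these calls. No variance trend gave 66 rises and 23 falls in hypoxia, adjusted p under 0.01 gave 119 and 46, and limma-treat against 0.5 gave 114 and 40, with 244 falls in anoxia. All clusters in the fit gave 151 and 76 in hypoxia. Any size gave 677 and 874 in hypoxia and 1259 and 1858 in anoxia, as the lower bar itself allows. Between anoxia and hypoxia, where 0 were called, median-centred arrays gave 66 higher and 16 lower, quantile normalization 19 higher, and cyclic loess 54 and 5. By size against each normoxia array, 1.5-fold gave 593 higher and 665 lower in hypoxia and 876 and 1187 in anoxia, and 3-fold gave 60, 19, 143 and 43. Leaving out each normoxia array gave 172 to 239 genes lower in hypoxia, 343 to 483 lower in anoxia and a correlation of 0.804 to 0.834; the counts grew because only 1 array then bounds each change. The correlation was 0.888 in the upper part of the genes by expression. The interferon-stimulated median in anoxia was -0.15 there, and ran from -0.041 to 0.234 when each normoxia array was left out. Where no reason is given, the cause was not tested. No paired analysis was possible because only the normoxia group has replicate numbers. Leaving out a normoxia array leaves no residual degree of freedom, so limma gave no value there. Clusters with shared-probe name endings could not be left out, since the names carry none. Signal over background was not measured, so changes of dim genes such as CXCL8 carry an unknown floor.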

Other observations

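The gene families and genes in this part were chosen after their values were seen, and so were their comparisons. Genes of mitochondrial ribosomal proteins, which make the ribosome of that organelle, had a median of -0.25 in hypoxia (65 of 73 below 0, percentile 0.01) and -0.41 in anoxia (72 of 73 below 0, percentile 0), and 0 of 73 were called in either. MRPL4 stood lowest in anoxia at -0.96. Genes of mitochondrial protein import (TIMM and TOMM) had medians of -0.31 and -0.48, and TIMM10 (-1.32 ± 0.11, SE) and TIMM8A (-1.08 ± 0.16) fell in anoxia, 2 of 23. Both families kept these directions under median centring, quantile normalization and cyclic loess. Cytosolic ribosomal protein genes had medians of 0.03 in hypoxia, which became -0.04 on median-centred arrays, and 0.07 in anoxia.

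Kruppel-like factor genes, which encode zinc-finger transcription factors, had a median of 0.34 in hypoxia and 0.71 in anoxia over 17 genes, positive under all 3 scalings. KLF11, KLF6 and KLF7 rose in hypoxia (1.32 ± 0.11, 1.07 ± 0.11 and 1.13 ± 0.19, SE). In anoxia 6 rose, KLF7 most (1.86 ± 0.19), with KLF4, KLF5 and KLF12 beside the former 3. Kinetochore genes of the CENP series had medians of -0.48 and -1.08, and 9 of 16 fell in anoxia, among them CENPU (-1.44 ± 0.16) and CENPM (-1.43 ± 0.16). Among genes that rose in anoxia, CCL2 stood at -0.05 ± 0.17 in hypoxia and rose by 2.29 ± 0.17 in anoxia, the immediate-early genes FOSB and ARC stood at 0.17 and 0.24 and rose by 1.61 and 1.73, and TREM1 stood at 0.36 and rose by 1.77. None of these passed the test between anoxia and hypoxia, where limma adjusted p ran from 0.182 for CCL2 to 0.201 for the others. CCL2, FOSB and ARC were called higher in anoxia after cyclic loess, median centring and quantile normalization, and TREM1 after cyclic loess and median centring. The tRNA synthetase genes had medians of 0.07, which was -0.01 on median-centred arrays, and 0.23, with 0 of 16 called. Against normoxia replicate 1 alone these medians were 0.11 and 0.26, and against replicate 2 alone -0.002 and 0.15. Zinc finger genes of the ZNF series had medians of 0.04, which was -0.04 on median-centred arrays, and 0.00 over 471 genes. Against replicate 1 alone they were 0.07 and 0.02, and against replicate 2 alone 0.0008 and -0.02.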
